A study of Mus musculus with 6 samples.

How the data were processed

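ATAC-seq was done on 6 libraries of mouse non-small cell lung cancer organoids, 3 from cultures sensitive to immunotherapy and 3 from resistant ones, as their labels give. Per the labels, nuclei were treated with a commercial transposase, the fragments were amplified with the number of cycles set by quantitative PCR, and read pairs were sequenced on a NovaSeq. The tools listed in the submitters' processing notes, with no role stated, are Bowtie2 2.2.1, SAMtools 1.8, GATK 4.1.3, deepTools, featureCounts, R 3.6.1, ChIPseeker 1.22.1 and DESeq2 1.26.0, with the mouse build mm10. The peak caller, the removal of duplicates and any shift of reads for the Tn5 cut are not given in the sources used here. Duplicates that were kept would make counts look more precise than they are, and shifts of a few bases would matter little for peaks of this width.

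The authors deposited 1 table, with 214414 peaks and the result of their own DESeq2 comparison of resistant and sensitive organoids. The authors' values per peak are the mean normalized count over all libraries (a signal), the log2 fold change and its standard error (both on the log2 scale), the Wald statistic (a score), and the p-value and adjusted p-value. The authors also give the peak width and the distance to the nearest transcription start, both in bp, and a ChIPseeker annotation. In the deposited table the statistic equals the fold change divided by its error (largest difference 8.7e-14), and the adjusted p equals the Benjamini-Hochberg value over the 102173 peaks that have one (largest difference 2.1e-15). The other 112241 peaks have none, and all but 2 of them lie under a mean normalized count of 14.7, as the independent filtering of DESeq2 leaves in the authors' output. The 6 columns of values per library fall into 2 sets of 3 by name, but the names match no sample label and do not say which set is resistant, so they were not used, and neither was a column of scores. All results therefore start from the authors' own fold changes and errors, and the sign, positive for higher in resistant organoids, rests on the title of the deposited table. If the title had the order the other way, every direction would turn. Depth per library was not analysed here. Peaks had a median width of 1301 bp (2211 bp among tested ones), 9084 tested peaks were over 5 kb wide, and the widest spanned 3103541 bp, so some entries are merged regions. Of 21199 gene identifiers in the annotation, 21186 were found in RefSeq's gene table.

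The design fixed before the data were examined assumed counts per library and a fit of its own to them. Since the deposited values are a finished comparison, the tests were adapted to it. Peaks with an adjusted p under 0.05 in the deposited table count as called. For promoters, each gene was represented by the promoter peak (within 3 kb of the start, as the deposited annotation has it) with the highest mean count, 15490 genes in all. Gene lists were tested with limma 3.58.1 (pre-ranked camera, preset correlation 0.01, in R 4.3.3) on the deposited Wald statistics, two-sided, with Benjamini-Hochberg adjustment over 27 lists written before the data were examined. Medians of lists have 95% bootstrap intervals over genes (10000 resamples) and a percentile among 10000 random lists drawn from the same deciles of mean count. Promoter odds used Fisher's exact test, two-sided, with Woolf intervals. Regional shifts were measured as the median log2 fold change of tested peaks per chromosome and per 5 Mb window with at least 20 of them, 485 windows. For the regional correction that median (of the chromosome in thinner windows) was subtracted from each deposited fold change, the deposited error was kept, and a normal test with Benjamini-Hochberg adjustment was repeated. The error of the window median was not added. Segments are at least 2 adjacent windows with a median of at least 0.6 in size, a limit chosen after the windows were seen. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and statsmodels 0.14.6 were used.

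The correction and list test were tested on simulated data with the real positions and errors, chromosome shifts of known size and 200 changed promoters. After the correction 51 of 100 promoters at a log2 change of 1 and 96 of 100 at 2 were recovered, and 13 of 166 calls were false (7.83%), while 5074 of 101902 unchanged peaks were called without it. Of the lists, camera found only the 2 that had been shifted. Each simulated chromosome had a constant shift and no trend with mean count. False calls in windows with a step inside, or from such a trend, were therefore not tested.

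Genes to name were fixed as a rule before the data were examined. They were the 6 called peaks and the 6 called promoters with the largest change each way among those above the median mean count (26.1), each gene once and without predicted genes, up to 2 members per list and direction with the smallest p, and all called collagens. The rule also asked for groups that do not overlap between libraries, which could not be applied. A few results that the rule or a search of gene families gave are not reported here. Cd47, Cd200 and Cd86 on chromosome 16 and the genes at the interval and steps given under the other observations were chosen after their values were seen.

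Alternatives were no filter on low counts, removal of a lowess trend (span 0.2) of fold change on mean count, removal of the 5 Mb shift, a change of at least 2-fold, a mean count of at least 50, and promoters within 1 kb. Others were added after seeing the data, namely both corrections together, removal of the median of the 10 nearest peaks of other genes on each side, centring on the median peak, peaks up to 5 kb wide, the 15 chromosomes with a median within 0.25 of 0, the strongest peak of any class per gene, camera on ranks, and for the chromosomes promoter peaks only and all peaks with a p. Motif enrichment and a correction for GC content need a genome sequence, which was not used here.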

Results

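Accessible chromatin was profiled by ATAC-seq, in which a transposase cuts and tags open DNA, in organoids of mouse non-small cell lung cancer. Organoids are tumour cells grown as 3-dimensional cultures. There were 3 libraries of organoids sensitive to immunotherapy and 3 of resistant organoids, and the comparison of these groups is the only 1 in the series. It addresses how open chromatin differs between organoids resistant and sensitive to immunotherapy, with collagens made by the cancer cells named in the title of the study. Other differences between the cultures of the groups cannot be separated from resistance. The authors' deposited table holds 214414 peaks on the mouse genome build mm10 with the log2 fold change between the groups, its standard error, a p-value and a gene annotation. Positive values were taken as higher in resistant organoids, which rests on the title of the table alone. The depth of each library was not analysed here. The precision is that of the standard errors, whose median in the authors' deposited table was 0.35 on the log2 scale over the 102173 tested peaks. It was 0.45 in the lowest decile of mean counts and 0.19 in the highest. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

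Peaks that were higher in resistant organoids included peaks at matrix and mesenchymal genes, and lower peaks included some at epithelial genes. Of 245 peaks of any class assigned to epithelial identity genes, 84 were lower and 1 higher in the authors' deposited table. Of 222 assigned to mesenchymal transition genes, 79 were higher and 4 lower there, with 25 of the higher ones on chromosome 16. In the authors' deposited table, 5124 peaks were higher in resistant organoids and 7503 were lower at an adjusted p under 0.05, which is 12.4% of those tested. A change of at least 2-fold was reached by 3725 of the higher and 3529 of the lower peaks. The largest increase in the authors' deposited table among called peaks above the median count, predicted genes left out, was in an intron of Grin2a, a glutamate receptor subunit, at chromosome 16, 9980290 to 9981700, with a log2 fold change of 2.96 ± 0.38 (SE). An intronic peak of Fstl1, a secreted glycoprotein gene, at chromosome 16, 37783420 to 37791750, gained 2.48 ± 0.17 (SE) in the authors' deposited table. Intergenic and intronic peaks of Flrt2 and Ccdc80 and the promoters of the long non-coding RNA gene Carmn and of Fbn2, a microfibril gene, rose by 2.24 to 2.39 in the authors' deposited table. The largest decreases in the authors' deposited table, among called peaks above the median count with 1 peak per gene and predicted genes left out, were in an intergenic peak assigned to Nrip1 (-2.76 ± 0.35 (SE); chromosome 16, 76241980 to 76244950), an intergenic peak upstream of Ets2 (-2.73 ± 0.27 (SE)) and a promoter peak of Tmprss2, an epithelial serine protease (-2.69 ± 0.23 (SE); chromosome 16, 97590590 to 97596240). Peaks assigned to Tshz2, Lingo2 and Stim2 fell by 2.67, 2.58 and 2.56 on the log2 scale in the authors' deposited table. Of these 12 peaks, 6 lie on chromosome 16, and all 12 kept an adjusted p under 0.05 after the median of their 5 Mb window was subtracted. On chromosome 16, Grin2a, Fstl1 and Ccdc80 were then at 2.28, 1.05 and 1.15, and Nrip1, Ets2 and Tmprss2 at -1.37, -1.51 and -1.48. After that subtraction 1939 peaks were called higher and 4035 lower. Of the calls in the authors' deposited table, 38.9% passed in the same direction, 1508 higher and 3399 lower. Another 1056 peaks were called only after the subtraction, and 11 were called in the opposite direction.

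Each of 15490 genes was represented by its strongest promoter peak. Of these promoters, 555 were higher and 2151 lower in resistant organoids in the authors' deposited table, and the median of all was -0.18. Higher promoters were 20.5% of the called ones, against 51.0% once a trend of fold change with mean count was removed, and for peaks these shares were 40.6% and 57.6%. With the regional shift removed as well, they were 39.4% for promoters and 41.6% for peaks. The promoters of Carmn, which hosts smooth muscle microRNAs (2.26 ± 0.22 (SE); chromosome 18, 61664010 to 61667120), and Fbn2 (2.24 ± 0.35 (SE)) gained most in the authors' deposited table among called promoters above the median count, predicted genes left out. Flrt2, Ccdc80, Twist1 and Cntnap4 followed with gains of 2.01 to 2.07 in the authors' deposited table. The microRNA gene Mir6384 (-2.35 ± 0.25 (SE)), the junction scaffold gene Afdn (-2.31 ± 0.47 (SE)) and the tight junction gene Cldn3 (-2.19 ± 0.16 (SE); chromosome 5, 134980500 to 134994180) lost most in the authors' deposited table by the same rule. Kcnk1, the epithelial splicing factor Esrp1 and Tmprss2 fell by 2.17, 2.06 and 1.98 on the log2 scale there. Without their windows' medians they were at -1.88, -1.94 and -0.77. Among the tested peaks of the authors' deposited table, 10.2% of promoter peaks were lower and 3.80% higher, against 5.84% and 5.64% of distal intergenic peaks. The odds of lying in a promoter were 1.68 times (95% interval 1.60 to 1.76, Fisher's exact p = 4.3e-93) those of uncalled peaks for lower peaks and 0.711 times (0.664 to 0.761, Fisher's exact p = 1e-23) for higher ones. Peaks are not independent, so these p-values are too small. The ratio for lower peaks was 0.682 among peaks with a mean count of at least 50 and 0.968 at a change of at least 2-fold, and that for higher peaks was 1.10 with no filter on low counts. At equal mean count promoters and other peaks had similar medians, as the plot of fold change by peak strength shows.

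**Figure D1:**
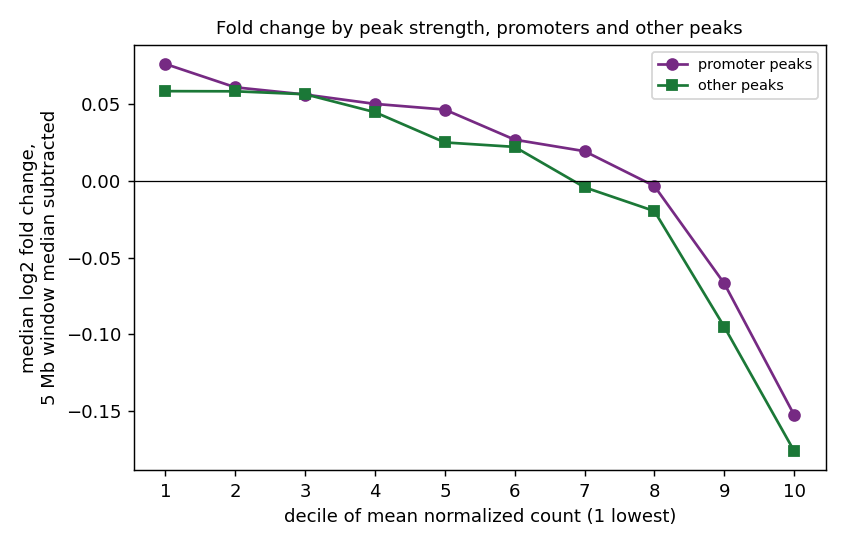
Median log2 fold change (resistant vs sensitive) of tested peaks after the median of their 5 Mb window was subtracted, by decile of the mean normalized count, for promoter peaks (circles) and other peaks (squares). Both lines fall from about 0.06 to 0.08 in the lowest decile to -0.15 and -0.18 in the highest.

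Collagen promoters that changed were higher in resistant organoids, and 24 of the 34 measured did not pass the test. Of 34 collagen chain genes measured, 10 were higher and 0 lower in the authors' deposited table, with 12 and 0 adjusted over the list alone and 13 and 3 at an unadjusted p under 0.05. The fibrillar chains Col1a2 (1.53 ± 0.46 (SE); chromosome 6, 4505900 to 4507210) and Col5a1 (1.38 ± 0.22 (SE); chromosome 2, 27885180 to 27890090) and the beaded-filament chain Col6a3 (1.31 ± 0.24 (SE)) rose most among the called ones in the authors' deposited table. The others past the threshold in the authors' deposited table were Col5a3, Col11a1, Col6a2, Col3a1, Col6a1, Col7a1 and Col8a2, with gains of 0.65 to 1.21. The Col1a2 peak had a mean count of 15.6, close to the lowest among tested peaks, 14.7. Col1a1 was at -0.01 with a mean count of 55 and did not pass. The list had a median of 0.11 (95% bootstrap interval -0.08 to 0.66; -0.10 at a mean count of at least 50), above 99.6% of random lists matched for mean count, and limma's camera put it above other promoters (adjusted p = 3.96e-05). The median was 0.22 after the 5 Mb window medians were subtracted, with an adjusted p of 5.4e-07 (5.4e-07 to 0.0268 over the alternatives), and 7 of the 10 promoters kept their call. The others, Col1a2, Col7a1 and Col8a2, were at 1.32, 0.75 and 0.62 after the subtraction, close to their uncorrected values. After subtraction of the median of the 20 nearest peaks of other genes, 5 kept it, namely Col5a1, Col6a3, Col11a1, Col5a3 and Col7a1, and the list's median was 0.26 (adjusted p = 6.25e-06). Among 27 genes of collagen processing and crosslinking, 6 were higher and 1 lower, with 6 and 1 adjusted over the list alone (median 0.10, camera upward, adjusted p = 0.0142). That call was lost at a mean count of at least 50 (median -0.19, adjusted p = 0.499) and with the strongest peak of any class (0.0597). The lowest adjusted p over its alternatives was 0.000751. They include Plod1, a lysyl hydroxylase (1.06 ± 0.29 (SE)), and Adamts14, a procollagen protease (1.08 ± 0.33 (SE)), while Adamts3 of the same family was at -0.95 ± 0.31 (SE) in the authors' deposited table. Adamts3 was at -0.29, not past the threshold, without its window's median. Other matrix proteins went both ways, with 5 higher and 5 lower of 42 in the authors' deposited table and 6 and 6 adjusted over the list alone (median 0.08, camera upward, adjusted p = 0.0117). That call too was lost at a mean count of at least 50 (median -0.11, adjusted p = 0.577) and with the strongest peak of any class (0.161). The lowest adjusted p over its alternatives was 0.000323. The microfibril genes Fbn2 and Fbn1 gained 2.24 and 1.91, and Thbs3 and the basement membrane gene Lama5 fell by 0.53 and 0.50 on the log2 scale in the authors' deposited table. Lama5 was at 0.06 with the regional shift and the abundance trend both removed.

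Most epithelial promoters measured were lower in resistant organoids, and the mesenchymal promoters that changed were higher in all but 1 case. Of 37 epithelial identity genes, 31 were lower and 0 higher in the authors' deposited table, with 33 and 0 both adjusted over the list alone and at an unadjusted p under 0.05. The list had a median of -1.03 (95% bootstrap interval over genes -1.25 to -0.85) and lay below other promoters (camera, adjusted p = 3.61e-36). Cldn3 and the keratin gene Krt19 (-1.63 ± 0.13 (SE); chromosome 11, 100137610 to 100161820) had the smallest p in the authors' deposited table. Of 26 mesenchymal transition genes, 11 were higher and 1 lower in the authors' deposited table, with 11 and 1 adjusted over the list alone (median 0.42, camera adjusted p = 1.13e-13). Snai2, a transcription factor that represses E-cadherin, gained 1.47 ± 0.21 (SE) and the mesoderm factor Twist1 gained 2.03 ± 0.34 (SE) in the authors' deposited table, and Zeb2 was the member that fell, by 0.78. Zeb2 was at -0.54, not past the threshold, without its window's median. Snai2 was at 0.79 and Twist1 at 1.63, both still past the threshold, without theirs. The promoter of Fstl1 gained 1.91 ± 0.17 (SE) in the authors' deposited table, and was at 0.49, no longer past the threshold, once its window's median was subtracted. After that subtraction 30 of the 31 epithelial and 7 of the 11 mesenchymal calls were kept, and the medians of the lists were -0.90 and 0.52. With the abundance trend removed as well, 23 and 9 were kept, and the medians were -0.62 and 0.68. The epithelial median was -0.53 with peaks up to 5 kb wide (camera adjusted p = 4.41e-06). Some of the peaks taken for epithelial promoters are broad, among them those of Krt19 and Cldn3 (chromosome 5, 134980500 to 134994180). These reach beyond the 3 kb that define a promoter here, so their values cover more than the promoter. The fibroblast markers, given with the other cell types, had a median of 0.16, and of 0.42 with the window medians subtracted. Alveolar and airway lineage genes were lower in 10 and higher in 2 of 25 promoters, with 13 and 3 adjusted over the list alone (median -0.57, camera adjusted p = 0.013). The call was lost with peaks up to 5 kb wide (adjusted p = 0.171) and with the strongest peak of any class (0.0792). The lowest over its alternatives was 0.000323. Foxa2, a factor of lung and gut epithelium, fell by 1.24 and the phosphate transporter gene Slc34a2 by 1.08 on the log2 scale in the authors' deposited table, while Foxa1 (0.54 ± 0.14 (SE)) and the alveolar type 1 marker Pdpn (0.96 ± 0.34 (SE)) rose. Foxa1 was at 0.07 without its window's median.

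**Figure D2:**
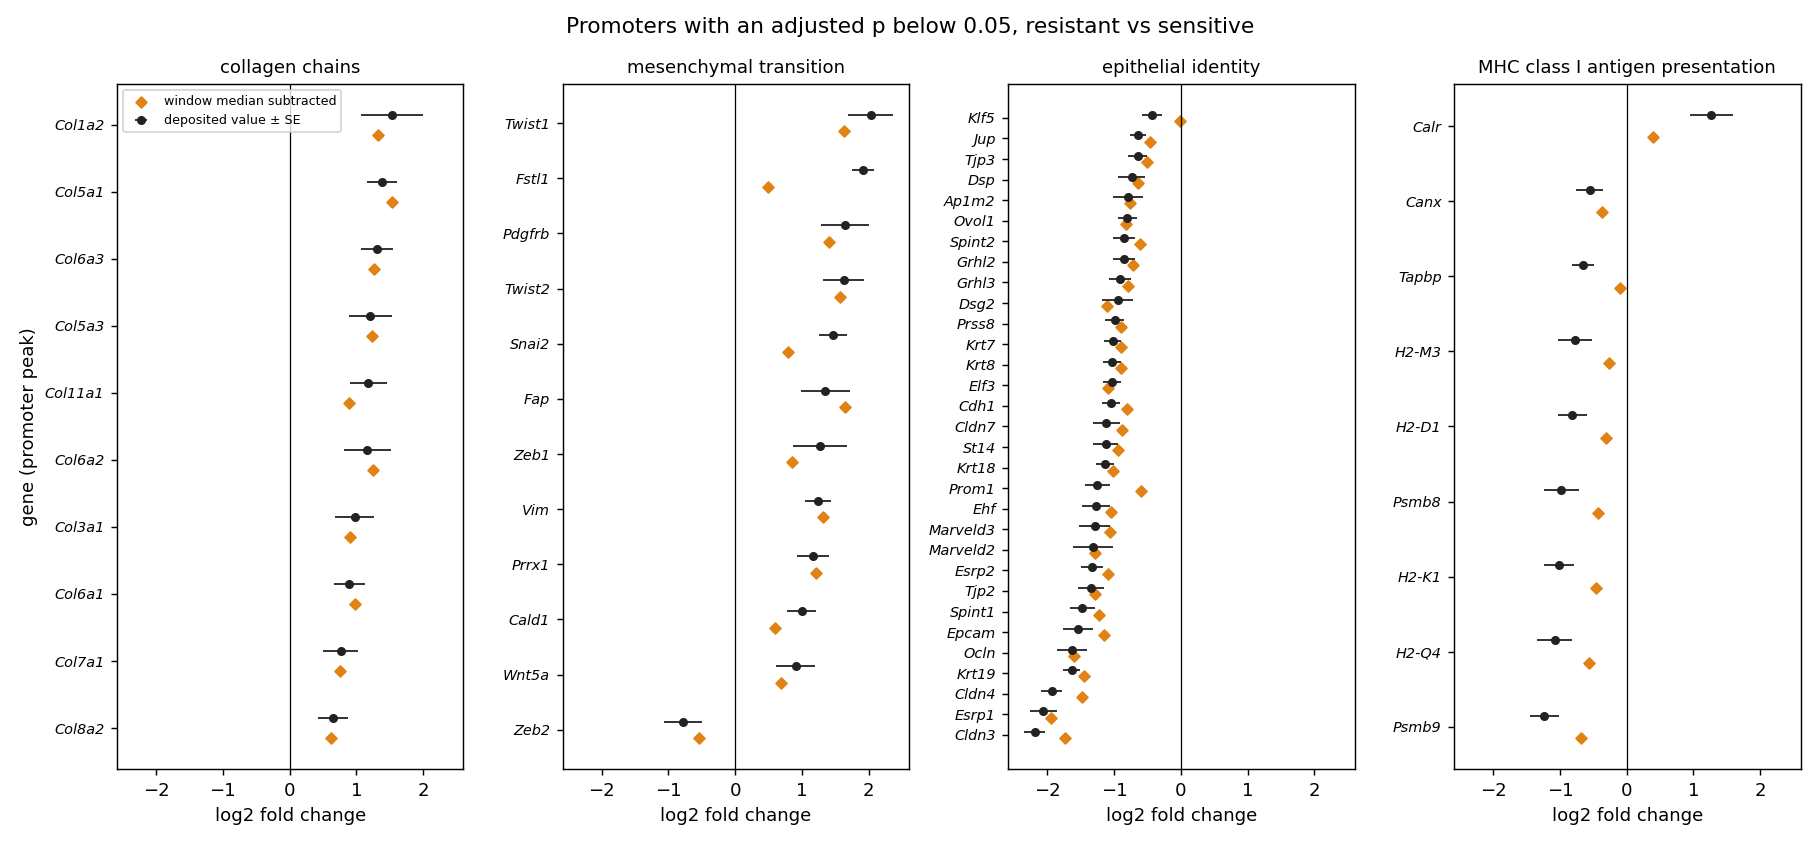
Log2 fold change (resistant vs sensitive) of the promoters with an adjusted p under 0.05 in 4 gene lists. Circles with bars are values of the authors' deposited table ± SE, and diamonds are the values after the median of the 5 Mb window was subtracted. The MHC class I genes move toward 0, such as H2-K1 from -1.01 to -0.46, while the epithelial genes move less, such as Cldn3 from -2.19 to -1.74.

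Among promoters of antigen presentation and interferon genes, more were lower than higher in resistant organoids, and most in each list did not pass the test. Of 20 MHC class I genes, 8 were lower and 1 higher in the authors' deposited table, with 9 and 1 adjusted over the list alone (median -0.52, camera adjusted p = 0.0163). The immunoproteasome gene Psmb9 fell by 1.23 and the class I heavy chain gene H2-K1 by 1.01 on the log2 scale in the authors' deposited table, and the chaperone gene Calr, which lies in a segment of chromosome 8 that was higher as a whole, gained 1.27 ± 0.32 (SE). With the window medians subtracted the list's median was -0.13 (camera adjusted p = 0.60, and 0.00162 to 0.949 over the alternatives) and 1 of the 8 lower calls, Psmb9, was kept. Calr was then at 0.40 and not past the threshold. Of 44 interferon response genes, 14 were lower and 1 higher in the authors' deposited table, with 19 and 1 adjusted over the list alone (median -0.41, camera adjusted p = 0.00105). The antiviral gene Mx1 (-1.65 ± 0.23 (SE); chromosome 16, 97458550 to 97465320) and the receptor gene Ifngr2 (-1.52 ± 0.20 (SE)) had the smallest p among these losses in the authors' deposited table, and Socs1, an inhibitor of cytokine signalling, gained 0.73 ± 0.16 (SE). Corrected for their windows these were at -0.44, -0.44 and 0.06, and 4 of the 14 lower calls were kept, with a median of -0.28 (95% bootstrap interval -0.46 to -0.14) and an adjusted p of 0.00122 for the list. That p was 0.0598 with the 20 nearest peaks subtracted (median -0.19) and 0.217 on chromosomes with a small shift, where the median was -0.35 (0.000161 to 0.217 over the alternatives). Chemokines and cytokines were lower in 11 and higher in 2 of 33 promoters, with 14 and 2 adjusted over the list alone (median -0.36, camera downward, adjusted p = 0.0117; 0.581 with the window medians subtracted and 0.0011 to 0.702 over the alternatives). The lower Cxcl2, Cxcl3, Cxcl5, Cxcl10 and Cxcl15 lie in the same window of chromosome 5, which had a median of -0.63. Cxcl1, Cxcl9 and Cxcl11 in that window did not pass. The preset correlation treats such neighbours as nearly independent, so the uncorrected p of this list may be too small. Tnf fell by 1.76 on the log2 scale and the neutrophil attractant Cxcl3 was 2.33-fold lower in the authors' deposited table, while the monocyte attractant Ccl2 gained 1.28 ± 0.39 (SE) and Tslp 0.91 ± 0.32 (SE). Tslp was at 0.80 and not past the threshold without its window's median. A list written in advance as T-cell inhibitory ligands had 25 genes measured, and what each member does to T cells was not tested. Of their promoters, 4 were higher and 6 lower, with 4 and 7 adjusted over the list alone (median -0.14, camera upward, adjusted p = 0.308). With the window medians subtracted, 0 were higher and 6 lower, and the test pointed downward (median -0.34, camera adjusted p = 0.094). Only 4 of the lower calls in the authors' deposited table were among these 6. The promoter of Cd200 was at 0.03 and not past the threshold in the authors' deposited table. It lies in a window of chromosome 16 with a median of 1.24, so the subtraction by itself moves it below 0. Nectin3 and Cd80 gained 1.76 ± 0.18 (SE) and 1.73 ± 0.19 (SE) in the authors' deposited table, and Nectin2 and Ceacam1 fell by 0.89 and 1.18. Over peaks of any class assigned to these ligand genes, 136 of 305 were higher and 13 lower in the authors' deposited table, and 135 of the 136 lie on chromosome 16, at Nectin3, Cd80, Cd47, Cd200 and Cd86. Nectin3 was at 0.52 and Cd80 at 0.31, neither past the threshold, after their windows' medians were subtracted. Cd47, Cd200 and Cd86 were chosen after their values were seen.

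**Figure D3:**
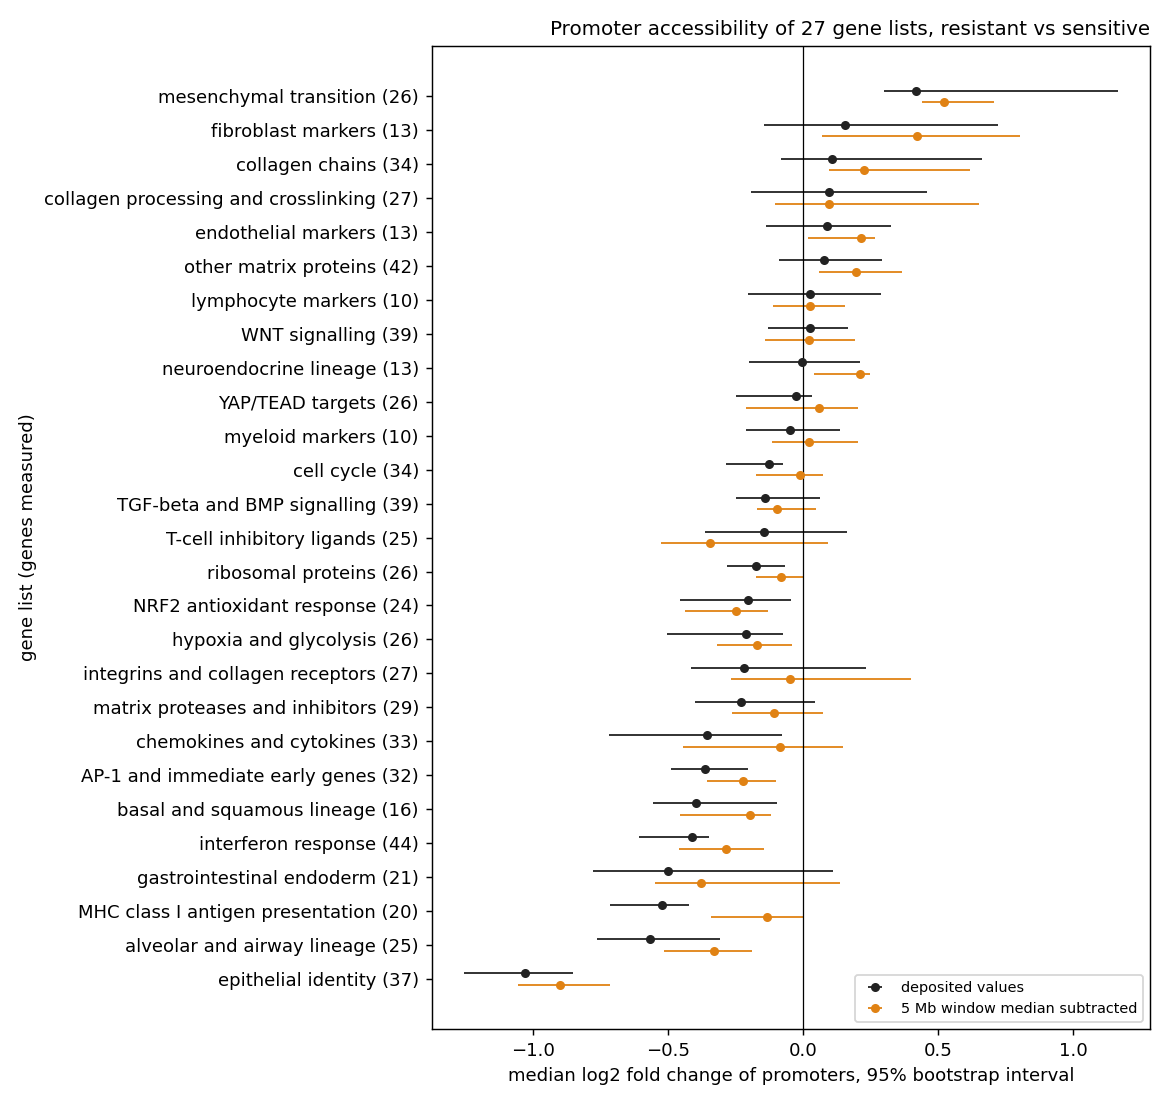
Median log2 fold change (resistant vs sensitive) of promoters in each of 27 gene lists, with the number of genes measured in brackets and bars for the 95% bootstrap interval over genes, for values of the authors' deposited table (black) and with the median of the 5 Mb window subtracted (orange). Epithelial identity is lowest at -1.03 and -0.90, mesenchymal transition is highest at 0.42 and 0.52, and MHC class I moves from -0.52 to -0.13.

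No other list passed the camera test on the values of the authors' deposited table. Promoters of AP-1 and immediate early genes were higher in 2 and lower in 12 of 32, with 2 and 16 adjusted over the list alone (median -0.36, adjusted p = 0.106). This list passed downward in 5 of 12 alternatives, among them with the window medians (adjusted p = 0.00781) or the 20 nearest peaks (0.0135) subtracted and on ranks (0.0357). It had an adjusted p of 0.553 with the abundance trend removed (0.00781 to 0.948 over the alternatives). Atf3 and Fosl2 fell by 0.75 and 0.72 on the log2 scale and Batf gained 1.18 ± 0.26 (SE) in the authors' deposited table. Ier2, at 0.40 ± 0.12 (SE) in the authors' deposited table, was at -0.46 once its window's median was subtracted. Gastrointestinal endoderm genes were lower in 7 and higher in 0 of 21 promoters, with 9 and 0 adjusted over the list alone and 10 and 1 at an unadjusted p under 0.05 (median -0.50, adjusted p = 0.0653; past the threshold in 5 of 12 alternatives, 0.00429 to 0.758). Tff1 fell by 1.68 in the authors' deposited table. Genes of hypoxia and glycolysis were lower in 6 and higher in 1 of 26 (8 and 1 adjusted over the list alone, median -0.21, adjusted p = 0.362), with Epas1, a hypoxia-inducible factor, at -1.14 ± 0.18 (SE) in the authors' deposited table. Of the integrins and collagen receptors, 3 of 27 were higher and 7 lower, with 5 and 7 adjusted over the list alone (median -0.22, adjusted p = 0.968), among them the fibronectin receptor gene Itga5 at 0.83 ± 0.18 (SE) and the laminin receptor gene Itga3 at -0.85 ± 0.15 (SE) in the authors' deposited table. Matrix proteases and inhibitors were higher in 2 and lower in 4 of 29 (2 and 7 adjusted over the list alone, median -0.23, adjusted p = 0.968), with Mmp19 at 0.89 ± 0.30 (SE) and Mmp15 at -1.12 ± 0.25 (SE) in the authors' deposited table. WNT signalling genes were higher in 3 and lower in 5 of 39, in both cases as when adjusted over the list alone (median 0.02, adjusted p = 0.224). Rnf43, which restrains WNT receptors, fell by 1.20 in the authors' deposited table. TGF-beta and BMP genes were higher in 2 and lower in 4 of 39, with the same counts adjusted over the list alone (median -0.14, adjusted p = 0.535). Tgif1 fell by 0.90 and Bmpr1b gained 1.28 ± 0.28 (SE) in the authors' deposited table. YAP/TEAD targets were higher in 2 and lower in 3 of 26 (3 and 5 adjusted over the list alone, median -0.025, adjusted p = 0.596; upward past the threshold in 1 of 12 alternatives, 0.022 to 0.839). Nuak2 fell by 0.80 and Tead3 by 0.76 in the authors' deposited table. NRF2 antioxidant genes were higher in 1 and lower in 3 of 24 (2 and 6 adjusted over the list alone, median -0.20, adjusted p = 0.968), with Nqo1 at 0.79 ± 0.26 (SE) and Osgin1 at -0.89 ± 0.14 (SE) in the authors' deposited table. Basal and squamous genes were lower in 2 and higher in 0 of 16, with 2 and 0 adjusted over the list alone and 4 and 0 at an unadjusted p under 0.05 (median -0.39, adjusted p = 0.546). Sprr1a and Perp fell by 0.89 and 0.80 in the authors' deposited table. The neuroendocrine list had 1 higher and 0 lower of 13, both adjusted over all promoters and over the list alone, and 1 and 0 at an unadjusted p under 0.05 (median -0.0019, adjusted p = 0.224). The 1 was Chga at 0.75 ± 0.26 (SE) in the authors' deposited table. Cell cycle genes had 0 higher and 3 lower of 34, with 0 and 2 adjusted over the list alone and 0 and 7 at an unadjusted p under 0.05 (median -0.13, adjusted p = 0.968). Cdkn1a and Mcm7 fell by 0.70 in the authors' deposited table. With the window medians subtracted, Fosl2 (-0.16), Batf (0.58), Tead3 (-0.36), Perp (-0.49), Chga (0.14), Cdkn1a (-0.29) and Mcm7 (-0.18) no longer passed.

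Among markers of other cells that a culture could hold, the fibroblast ones passed the test most often. Of 13 fibroblast markers, 2 were higher and 2 lower in the authors' deposited table, with 4 and 2 adjusted over the list alone. Of all promoters, 3.58% were higher and 13.9% lower there. The fibroblast list had a median of 0.16 (camera adjusted p = 0.0559). With the window medians subtracted its median was 0.42 (camera upward, adjusted p = 0.00424). It passed in 6 of 12 alternatives (adjusted p 0.00424 to 0.939). Mgp and Pdgfrb gained 1.43 ± 0.29 (SE) and 1.64 ± 0.36 (SE) in the authors' deposited table, and Ly6a and Pi16 fell by 0.84 and 1.01. Pi16 was at -0.61 and not past the threshold without its window's median. These values stand beside the rises of the mesenchymal and collagen lists. Of 13 endothelial markers and 10 lymphocyte markers, 0 passed in the authors' deposited table or adjusted over each list alone, and 1 and 0 had an unadjusted p under 0.05 (medians 0.09 and 0.02, camera adjusted p = 0.224 for both). The endothelial list passed upward with the window medians (median 0.22, adjusted p = 0.0424) or the 20 nearest peaks (0.0206) subtracted. Its adjusted p was 0.0206 to 0.776 over the alternatives. Of 10 myeloid markers, 1 passed, Fcgr3 at -1.28 ± 0.37 (SE), in the authors' deposited table and adjusted over the list alone (median -0.05, camera adjusted p = 0.546). Ribosomal protein genes, taken as a reference, had 1 lower, Rpl5, and 0 higher of 26 promoters, 0 and 0 adjusted over the list alone, and 3 and 0 at an unadjusted p under 0.05 (median -0.17, camera adjusted p = 0.968). The camera test compares a list's Wald statistics with those of other promoters, not its median with 0. The integrin, T-cell ligand, TGF-beta, YAP/TEAD, neuroendocrine, myeloid and ribosomal lists had medians below 0 but pointed upward in the test, and the WNT list had a median of 0.02, a mean of -0.03 and an upward test. The camera test used a preset correlation of 0.01, and an estimated correlation was not run, since the values of single libraries were not analysed here.

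Whole chromosomes and long segments differed between the groups. In the authors' deposited table the median log2 fold change of tested peaks was 0.75 on chromosome 16, 0.53 on chromosome 12, -0.53 on chromosome 5, -0.43 on chromosome 17 and -0.41 on chromosome X, with interquartile ranges of -0.75 to -0.32 for chromosome 5 and 0.26 to 0.78 for chromosome 12. Chromosome 16 alone held 36.9% of all higher peaks and chromosome 12 held 15.1%, while chromosome 5 held 21.6% of all lower peaks. Chromosome 16 was made of steps. Its 0 to 15 Mb had a median of 0.68 and its 35 to 55 Mb a median of 1.35 (2.55-fold), with 1544 of 1980 tested peaks higher, and its 85 to 100 Mb a median of -1.14, with 244 of 367 peaks lower and 0 higher in the authors' deposited table. On chromosome 8 the 80 to 90 Mb segment had a median of 0.86 against -0.21 in the next 5 Mb. In the 444 windows of 5 Mb with at least 10 peaks of each kind, promoter and other peaks shifted together, with a slope of 0.88 of the promoter medians on the others (95% bootstrap interval over chromosomes 0.73 to 0.94). For chromosome 16 the median was 0.41 over promoter peaks and 0.84 over other peaks. The exact permutation of libraries planned for these shifts was not run, because no library values were used.

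**Figure D4:**
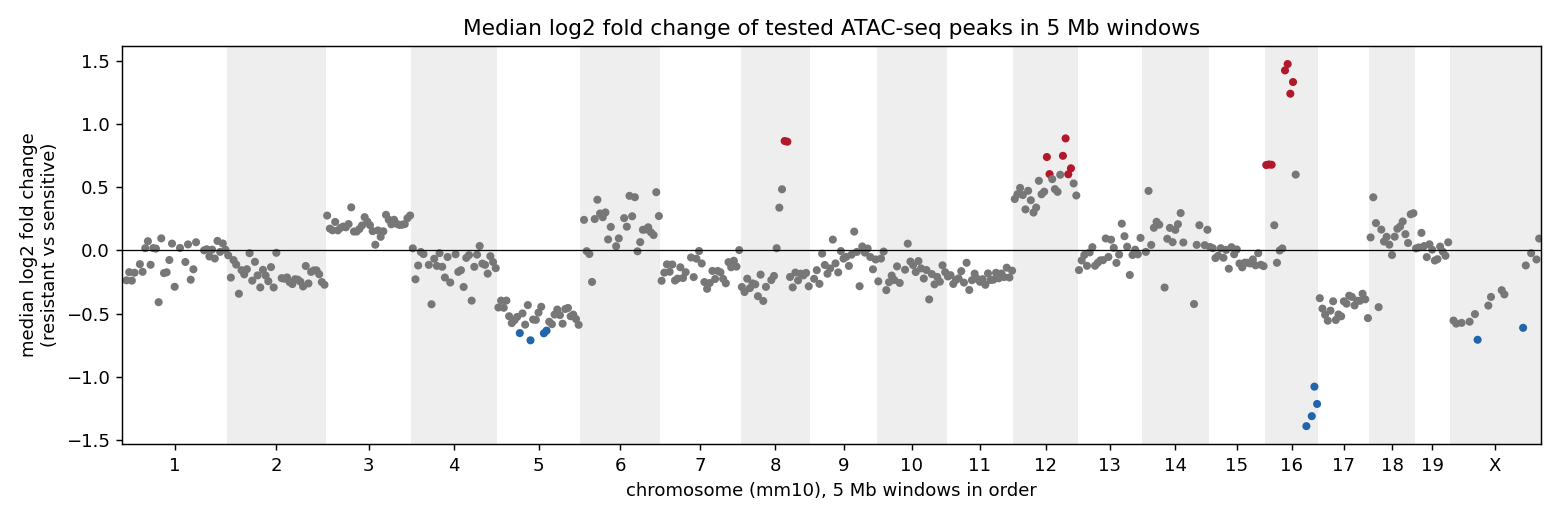
Median log2 fold change (resistant vs sensitive) of the tested peaks in each 5 Mb window with at least 20 of them, in genome order, 1 point per window. Red and blue mark medians of at least 0.6 and at most -0.6. Chromosome 16 rises to 1.47 and drops to -1.39, and chromosomes 5 and 17 lie below 0 throughout.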

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

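The settings with the nearest peaks, both corrections, centring, wide peaks left out, few-shift chromosomes, strongest peak of any class, ranks, promoter-only or all chromosome peaks, the count minimum for promoters, lists and odds, and the 2-fold limit for odds were chosen after the result was seen. The collagen, mesenchymal and epithelial lists kept their test direction and stayed past the threshold in the 12 alternatives run for each, with adjusted p of 5.4e-07 to 0.0268, 2.09e-16 to 2.14e-07 and 5.35e-45 to 4.41e-06, although the collagen median was -0.10 at a mean count of at least 50. No paired analysis was possible because the columns of single libraries match no sample label. Since these columns were not used, other size factors, library size alone, the replicate block, leaving out each library, an estimated correlation, fry, counts summed per gene and other splits of the libraries were not run. The trend planned as offsets was removed from fold changes instead. GC correction, motif enrichment and its alternatives (another background, whole peaks, other called sets) were not run without a genome. The median of promoters was -0.18 in the deposited values, 0.000293 with the abundance trend removed and -0.08 with the regional shift removed, and list tests are relative to it. Of 107 named promoters and peaks, 105 were called in the deposited table, all but Kdr and Bcl11b. After the regional correction 68 kept direction and call, 35 lost the call and 3 turned, among them the uncalled Bcl11b. Precision limits the weakest peaks, with a median SE of 0.45. Except where the construction removes peaks or raises a threshold, the cause was not tested.

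With the 5 Mb shift removed, 1939 peaks were higher and 4035 lower, and 265 promoters were higher and 1029 lower. The MHC class I median was -0.133 and no longer past the threshold. The test turned for T-cell ligands (-0.3434), cell cycle (-0.0101) and matrix proteases (-0.1085), and Bcl11b (-0.0037), Hif1a (-0.0394) and Ier2 (-0.4631) turned. With the 20 nearest peaks removed, counts were 1893 and 3861 for peaks and 261 and 1002 for promoters. The MHC class I (-0.1517) and interferon (-0.1917) lists lost their calls, T-cell ligands (-0.2707), cell cycle (-0.0451), matrix proteases (-0.0763) and ribosomal proteins (-0.1633) turned in the test, and so did Bcl11b (-0.1199), Chga (-0.0351), Hif1a (-0.0976) and Ier2 (-0.6435) in sign. With the abundance trend removed, 4746 peaks were lower, 1056 promoters higher and 1014 lower, and the odds ratio of higher peaks was 0.945. AP-1 (-0.0278), NRF2 (0.0782), cell cycle (0.104), hypoxia (-0.0182), matrix proteases (0.0032) and myeloid (0.0106) lists turned in the test. With both removed, 2169 peaks were higher and 3047 lower, 613 promoters were lower, and the odds ratio of higher peaks was 0.962. The MHC class I median was -0.0626, T-cell ligands (-0.196), cell cycle (0.1329), matrix proteases (0.0459) and myeloid markers (0.0699) turned in the test, and Bcl11b (-0.041), Fosl2 (0.0923), Ier2 (-0.1419), Lama5 (0.0613) and Mcm7 (0.0285) in sign.

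On chromosomes with a small shift, 2421 peaks were higher and 4606 lower, and 326 promoters higher and 1242 lower, of fewer tested. The interferon list (-0.3481) lost its call, and the test turned for MHC class I (-0.284), T-cell ligands (-0.3266), cell cycle (-0.1058), integrins (-0.2268) and ribosomal proteins (-0.1572). At a mean count of at least 50, 1540 peaks were higher and 4708 lower, the odds ratio of lower peaks was 0.682, and NRF2 (-0.1433), cell cycle (-0.1271) and fibroblast (0.0442) lists turned. At a change of at least 2-fold, 3529 peaks were lower, 253 promoters higher and 614 lower, and the odds ratio of lower peaks was 0.968. With no filter on low counts the odds ratio of higher peaks was 1.1, and integrins (-0.1536) and ribosomal proteins (-0.1722) turned. With peaks up to 5 kb wide, 1190 promoters were lower and the cell cycle list (-0.099) turned. With promoters within 1 kb and on ranks the cell cycle (-0.1271) and ribosomal (-0.1722) lists turned in the test, while their medians were those of the deposited values. For every list in these settings, turned means that the camera test changed direction, and the brackets hold the median. No list passed in a setting where it turned (camera adjusted p of at least 0.0739). With the strongest peak of any class, 833 genes were higher, and TGF-beta (-0.1779), cell cycle (-0.1176) and integrin (-0.2157) lists turned. Centred on the median peak, NRF2 (-0.1355) and cell cycle (-0.0583) lists turned.

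The medians of chromosomes 16, 12, 5 and 17 were 0.8167, 0.5985, -0.4634 and -0.3652 when centred, and 0.7041, 0.5952, -0.5138 and -0.4185 over all peaks with a p. Those of chromosomes 16, 12 and 5 were 0.4106, 0.4684 and -0.5609 over promoter peaks and 0.8381, 0.5443 and -0.5215 over other peaks.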

Other observations

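The tests on scaling, on peak strength, on fibroblast markers and on the epithelial, mesenchymal, MHC class I and interferon lists were chosen after the result was seen, and those on copy number, open chromatin and the collagen list before.

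An interval of chromosome 16 stood apart from its surroundings. From 35571110 to 35986010, all 11 tested peaks lay below 0 in the authors' deposited table, with a median log2 fold change of -1.445 and 9 of them past the threshold. They are assigned to Sema5b, Slc49a4, Hspbap1, Parp14, Parp9 and Kpna1, and Parp14 is in the interferon list. The 50 tested peaks before the interval had a median of 0.57 and the 50 after it a median of 0.99, with 0 of those after it below 0. Its edges were the largest of 13 steps of at least 1.5 between runs of 10 neighbouring peaks, at -2.05 and 2.49. Other steps lay at 82.1 and 90.1 Mb of chromosome 8, with medians of -0.39 before and 1.39 after the first, at Slc12a2 on chromosome 18, at Mitf on chromosome 6 and at Sgms1 on chromosome 19, where a run of 10 peaks at -1.67 lay between runs at 0.04 and 0.02. These steps were found by a search of the data, and whether they are edges of DNA segments was not tested.

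Peak density differed between chromosomes in the deposited peak list, which covers both groups. Chromosomes 15, 3, 12 and 5 held 161, 146, 121 and 120 peaks per Mb in the deposited table, against 59.1 on chromosome 1 and 43.1 on chromosome 14, and chromosome X held 6.71. Of the peaks on chromosome 3, 12.2% were promoters, against 29.5% on chromosome 7. The median mean count of the strongest promoter peaks per gene was 95.6 on chromosome 15 and 84.2 on chromosome 3, against 61.2 on chromosome 1 and 38.7 on chromosome X. Of these denser chromosomes, 15 had a median log2 fold change of -0.07, 3 of 0.18, 12 of 0.53 and 5 of -0.53, and the density in each group was not analysed here.

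The shifts of whole chromosomes and segments may reflect DNA copy number that differs between the organoid groups, since a change of copies moves all peaks of a region by about the same factor. Promoter medians followed those of other peaks over the windows with a slope of 0.88, which lies above the 0.8 set in advance for that explanation, but its 95% interval, 0.73 to 0.94, reaches below that bound and excludes 1, while it also excludes the 0.5 set against it. A regional change of chromatin confined to strong regulatory peaks would leave weak peaks behind. The medians of the weakest peaks (lowest quartile) followed those of the strongest (highest quartile) with a slope of 0.89 (0.79 to 1.00), which argues against such a change. Even the weakest quartile consists of peaks rather than background reads. A change of chromatin that moves weak and strong peaks of a region alike cannot be told from copy number by this slope. A single scaling factor per library cannot produce window medians whose SD was 5.48 times that of shuffled peaks. Copy number was not measured, and whether a gain arose with resistance or with the choice of cultures stays open.

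Strong peaks were lower in resistant organoids, with a median of -0.26 in the highest decile of mean counts against 0.02 in the lowest in the deposited table. A loss particular to promoters is argued against, since promoters lay 0.0143 above other peaks of the same decile on average, after the regional correction. Lower signal over background in resistant libraries could give this trend, and then ribosomal protein promoters should lie where the trend puts them, at -0.14. They had a median of -0.08 (95% interval -0.17 to 0.01), which is 0.0545 above the trend and cannot be told apart from it or from 0 with 26 genes. A global loss of strong sites in resistant cells stays open as well, since fragments in and outside peaks were not analysed here.

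The gene lists differ in how far regional shifts account for them. A regional shift as the whole cause is argued against for the collagen (0.22), mesenchymal (0.52) and epithelial (-0.90) lists, whose medians after subtraction of the window medians are given and whose camera calls were kept. For the MHC class I list the corrected median of -0.13, against -0.52 before (95% intervals -0.34 to 0.00 and -0.71 to -0.42), is what a regional shift needs, and the call ended because the median itself shrank. Members such as Psmb9 and H2-K1 share a window of chromosome 17 with a median of -0.55. A change of that locus itself would be subtracted too, and for such members it cannot be told apart from a regional shift. The interferon list at -0.28 stays undecided, since its call was lost against the 20 nearest peaks (adjusted p = 0.0598) and kept against windows (0.00122, or 0.0121 without Parp14, whose window holds the interval above; 0.000161 to 0.217 over the alternatives); the 0.217 on chromosomes with a small shift came with a median of -0.35. Fibroblasts in the resistant cultures could raise mesenchymal and collagen promoters, but the 10 fibroblast markers measured outside the mesenchymal and matrix lists, of the 13 in all, had a median of 0.11 (95% interval -0.49 to 0.72) with 1 higher and 2 lower, and Ly6a and Gsn, the ones with the highest mean counts, at -0.84 and 0.54, which cannot be told apart from the 0.42 of the mesenchymal list. With the window medians subtracted, these 10 had a median of 0.16. All 13 then had a median of 0.42 (95% interval 0.07 to 0.80) and passed upward (camera adjusted p = 0.00424). Fibroblasts in the resistant cultures therefore stay open.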
